A study of Mus musculus with 8 samples.

How the data were processed

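PRO-seq was performed on 8 libraries of E14 mouse embryonic stem cells: 2 controls, 2 treated with JQ1 for 2 h, and 2 each treated with 50 nM LBH589 for 2 h and 6 h. The groups are those of the sample labels. According to the submitters' processing notes, cutadapt and Bowtie2 were used with the mm10 build; their versions are not given in the sources used here. The 9 tables analysed here are comparisons computed by the authors, 3 for each of the 3 treatments against control. They hold no values per library, so that replicates, depth per sample and library quality could not be examined.

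The gene-body and enhancer tables deposited by the authors give a log2 fold change, its standard error, a test score, a p-value and an adjusted p, under the column names of a DESeq2 results table; the tool itself is not given in the sources used here. The log2 values in the authors' tables are treated over control. The signal in the authors' deposited tables, a mean normalised read count per gene body or enhancer, is pooled over the libraries of a comparison. The score in the authors' tables equals the log2 fold change over its standard error to within 9.2e-14, and the p-value deposited by the authors equals the two-sided normal p of that score, to within 2.9e-15. The largest standard errors of gene bodies, 0.574, 0.628 and 0.658 for LBH589 2 h, LBH589 6 h and JQ1, compare with 0.520, 0.587 and 0.633 at mean counts under 5, so the standard errors do not grow without limit at low counts, as fold changes drawn toward 0 would show. The pausing tables deposited by the authors give a log2 change, a p-value and a false discovery rate; the test and the windows of the index are not given in the sources used here, and 8, 7 and 46 p-values are exactly 0, which are not printed. Enhancers were listed separately for each comparison, with different numbers and boundaries.

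Each gene table has 20820 transcripts, with 118 symbols on more than 1 row, of which 11064, 11838 and 10778 had an adjusted p for gene bodies in LBH589 2 h, LBH589 6 h and JQ1. Transcript identifiers were joined to a RefSeq gene table (97.4% matched), and gene symbols are printed as deposited; 2199 differ from the RefSeq table, such as Fam40b, now Strip2. Fold changes, standard errors and calls of single genes and enhancers are the authors' own, with an adjusted p threshold of 0.05. Sox2 was not analysed here, and Esrrb had no test.

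Computed here were the following. The difference between 2 comparisons was the difference of their log2 fold changes over the root of the summed squared standard errors, with a two-sided normal p and Benjamini-Hochberg adjustment. Since both share the control libraries, this error is too large, and the alternative with the shared covariance subtracted is given beside it. Overlaps of calls were set beside independent lists and beside 100 simulated draws of unchanged groups that share control libraries, with 50% of each variance taken from the controls. The 43 gene lists (pathways, complexes, gene families, and markers of other cell types) were tested by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 252 tests. List medians were compared with 10000 random lists matched on mean level. The direction of enhancers was compared with that of the nearest tested gene, by GENCODE M21 transcription starts within 100 kb, and the direction of the pausing index with that of the gene body, by Fisher's exact test, two-sided. Tests across genes treat genes as independent, which they are not. Intervals of medians are from 2000 bootstrap draws over genes or enhancers.

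Genes named are, for each treatment, the 8 higher and 8 lower gene bodies with the smallest p-values and an absolute log2 fold change of at least 1, the 5 pausing rises and 5 falls with the smallest p-values (ties by the larger change), the 4 members of each list with the smallest p-values, and 16 genes fixed in advance. Enhancers named are the 5 higher and 5 lower with the smallest p-values. Also named are enhancers whose nearest gene, within 100 kb, was fixed in advance, at most the 2 with the smallest p-values per gene. The comparisons, tests, lists, rules for named genes and alternatives were fixed before the data were examined, except where stated. Alternatives were adjusted p thresholds of 0.01 and 0.1, a bound of 1 on the absolute log2 fold change, each table centred on its median, adjustment recomputed over all genes with a p, 1 row per gene symbol, the 25% of lowest mean level left out, other distances for enhancers, and the subtracted covariance. An overlap of at least 50% of both enhancers was added later, as were the simulated draws for enhancers and the promoter-proximal change with table medians set to 0.

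The difference test was tested on simulated data with the standard errors of the tables and shared control libraries. Planted differences of log2 1 were called at 12.5% of genes for LBH589 6 h against 2 h, and differences of log2 2 at 86.0%; none of the unchanged genes was called. The precision of the tables is limited by 2 libraries per group. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.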

Results

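Precision nuclear run-on sequencing (PRO-seq), which maps RNA polymerase engaged on DNA from labelled run-on transcripts, was carried out in E14 mouse embryonic stem cells grown without feeders in serum and LIF. There were 8 libraries in 4 groups of 2: untreated control, LBH589 (panobinostat, a histone deacetylase inhibitor) at 50 nM for 2 h and for 6 h, and JQ1, an inhibitor of BET bromodomain proteins such as BRD4, for 2 h. The labels give no JQ1 dose and name no vehicle. The stated purpose was to see the direct effects of HDAC and BRD4 inhibition on transcription in these cells. The 3 treatments were each set against the same 2 control libraries, and for each the authors deposited 3 tables, of gene-body transcription, pausing index and enhancer transcription. The tables hold no value per library, so the depth of each sample is unknown. The labels call the libraries duplicates and do not say that they came from separate cultures. The gene-body and enhancer p-values therefore measure only the spread between these samples. The test behind the pausing p-values is not given, so whether they measure a spread between libraries at all is unknown. All pausing calls and shares below rest on them. Unless stated otherwise, values are log2 fold changes of treated over control with the authors' standard error. Higher and lower mean an adjusted p under 0.05, and positions are on mm10. The gene-body medians were -0.0033, -0.012 and -0.0071 for LBH589 2 h, LBH589 6 h and JQ1. Gene bodies are thus higher or lower relative to the typical gene. If the scaling set these medians, a shift common to all genes would not show. Setting them to 0 cannot reveal such a shift.

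LBH589 for 2 h addressed the early effect of histone deacetylase inhibition, and genes of the pluripotency network lost gene-body transcription. Of the 38 measured genes of the pluripotency list, 28 were lower and 0 were higher (28 lower adjusted over the list alone), with a median log2 fold change of -1.24 (Fisher's exact test for lower genes, adjusted p = 1.5e-11). Nanog, a core pluripotency transcription factor (NM_028016, chromosome 6, 122707489 to 122714633), had a log2 fold change of -2.06 ± 0.22 (adjusted p = 1.3e-17) in the authors' deposited table. Pou5f1, which encodes OCT4 (NM_013633, chromosome 17, 35506032 to 35510777), stood at -1.50 ± 0.27 in the authors' deposited table. The same deposited table from the authors gave -1.62 ± 0.21 for Zfp42, a marker of the naive state, and -1.15 ± 0.27 for Klf4, a transcription factor of the naive network. The NODAL-pathway ligand Gdf3 (-2.87 ± 0.22) and co-receptor Tdgf1 (-2.54 ± 0.21), the transcription factor Sall1 (-2.27 ± 0.20) and the 5-methylcytosine oxidase Tet1 (-2.02 ± 0.18) were among the 8 lower genes with the smallest p-values in the authors' deposited table. The others of those 8 were Anp32b (-2.63 ± 0.21), cyclin D1, Ccnd1 (-2.58 ± 0.23), the branched-chain aminotransferase Bcat1 (-1.96 ± 0.18) and threonine dehydrogenase, Tdh (-2.04 ± 0.19), by the authors' deposited table.

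Genes for making ribosomes and for growth were lower as well. Of 73 ribosomal protein genes, 54 were lower and 0 were higher (61 lower adjusted over the list alone; median -0.73; adjusted p = 2.1e-22). Rpsa (-1.13 ± 0.20) and Rpl21 (-1.18 ± 0.21) had the smallest p-values of that list in the authors' deposited table. Random lists matched on gene length and mean level had a median of -0.56, so that other genes of this length and level lay below 0 too. No other list, and no list in the other treatments, was matched on gene length, so this limit may hold for those too. Of 41 genes of ribosome biogenesis, 25 were lower and 1 was higher (27 lower and 1 higher adjusted over the list alone; adjusted p = 1.1e-07), among them nucleolin, Ncl, at -1.31 ± 0.21 in the authors' deposited table. Lower genes were also over-represented among host genes of small nucleolar RNAs (7 of 10; 8 adjusted over the list alone; adjusted p = 0.0056) and genes of S phase and mitosis (17 of 36; 18 adjusted over the list alone; adjusted p = 0.0014). Among the cell cycle genes were the transcription factor Mybl2 (-1.48 ± 0.19) and the replication helicase subunit Mcm2 (-1.23 ± 0.21), per the authors' deposited table. Glycolysis (10 of 18 lower; 11 adjusted over the list alone; adjusted p = 0.0054) and the unfolded protein and integrated stress responses (10 of 20 lower; 12 adjusted over the list alone; adjusted p = 0.011) completed the lists with more lower genes. The glucose transporter Slc2a3 (-1.21 ± 0.18) and asparagine synthetase, Asns (-1.23 ± 0.20), were examples from the authors' deposited table.

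Higher genes were over-represented in the neuronal and synaptic list, with 11 of 22 higher and 1 lower (11 and 1 adjusted over the list alone; median 0.71; adjusted p = 0.0059). The calcium channel gene Cacna1b (1.86 ± 0.21) and the synaptic vesicle GTPase gene Rab3a (2.38 ± 0.32) led it in the authors' deposited table. Among 175 solute carrier genes 51 were higher and 34 lower (54 and 36 adjusted over the list alone; adjusted p for higher genes = 0.0035). Genes with a Zfp symbol, mostly zinc finger proteins, were higher less often than other genes, at 20 of 294 (18 adjusted over the list alone; adjusted p = 7.0e-07). The list of genes known to respond to HDAC inhibitors had 9 of 23 higher (9 adjusted over the list alone) and did not pass (adjusted p = 0.12). Its member H1f0, a linker histone gene, was at 1.46 ± 0.27 and Cdkn1a, the cell cycle inhibitor p21, at 0.75 ± 0.25 in the authors' deposited table. The 8 higher genes with the smallest p-values in the authors' deposited table were Tec, Col5a3 (2.96 ± 0.29), Fam40b (2.94 ± 0.29), Fstl3 (3.64 ± 0.36), Plekho2 (2.32 ± 0.23), D16H22S680E (1.98 ± 0.20), Tmem130 (2.74 ± 0.28) and Micu1 (1.76 ± 0.18). Tec, a non-receptor tyrosine kinase gene, was 5.67-fold higher by that table of the authors. Fstl3 encodes a secreted antagonist of activin and Micu1 a regulator of the mitochondrial calcium uniporter.

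In all, 2010 genes were higher and 2093 lower of 11064 with an adjusted p. With an absolute log2 fold change of at least 1 required, 885 were higher and 690 lower. Under that bound the lists of cell cycle (adjusted p = 0.29), glycolysis (adjusted p = 0.34), unfolded protein and integrated stress responses (adjusted p = 0.19), small nucleolar RNA hosts (adjusted p = 0.89) and neuronal genes (adjusted p = 0.055) no longer passed. The list of genes known to respond to BET inhibitors, with 6 of 14 lower (6 adjusted over the list alone; adjusted p = 0.14), passed for lower genes only under that bound (adjusted p = 0.016).

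**Figure D1:**
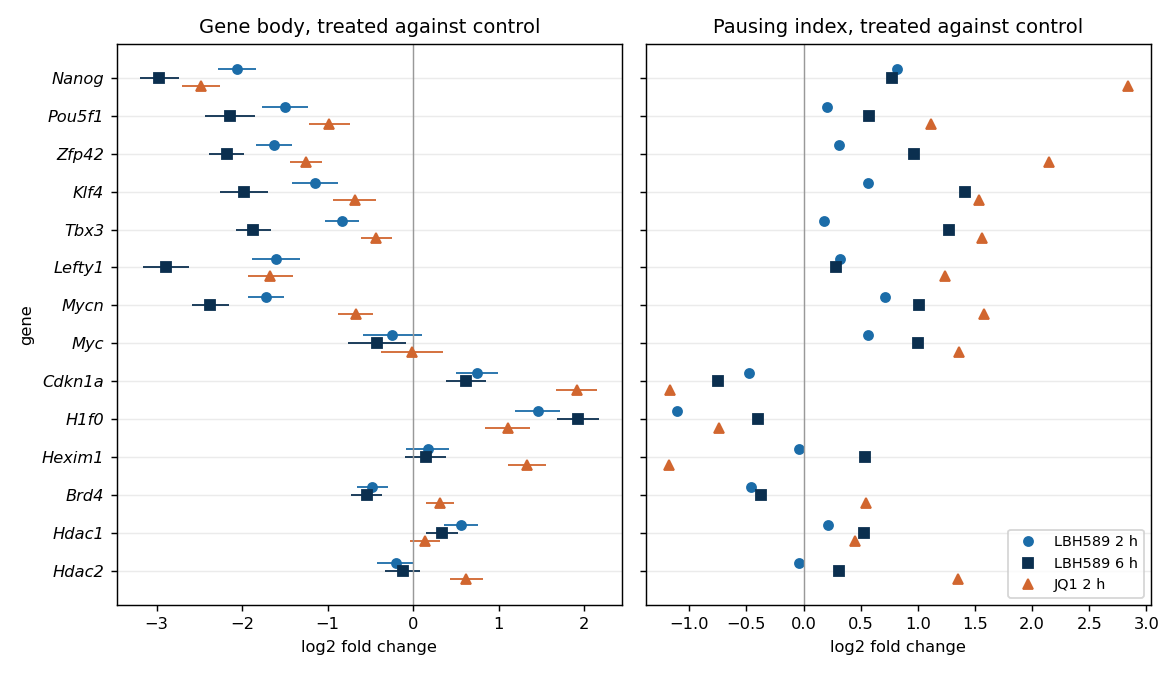
Gene-body (left) and pausing index (right) log2 fold changes of 14 genes fixed in advance, treated over control, one marker per treatment; bars are the authors' standard errors, which the pausing table does not give. Nanog lay at -2.06, -2.97 and -2.48 in gene bodies and at 0.81, 0.78 and 2.84 in pausing index for LBH589 2 h, LBH589 6 h and JQ1.

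The pausing index, by common definition the ratio of promoter-proximal to gene-body polymerase, moved differently at genes that gained and at genes that lost transcription. At 2010 higher genes it fell at 57.6% and rose at 7.81%. At 2093 lower genes it rose at 31.0% and fell at 27.9% (odds ratio 8.20, Fisher's exact test, p = 3.2e-113). Because the gene body is the denominator of the index, part of this relation is built into it. In the authors' deposited table the index rose at Nanog (0.81), Mycn (0.71), Klf4 (0.57) and Zfp42 (0.31), all pluripotency or MYC-family transcription factor genes, and fell at H1f0 (-1.11). With the smallest p-values in the authors' deposited table were rises at Eif4a2 (0.74), Rn45s (0.57), Brsk1 (2.13), Snhg1 (0.92) and Cecr2 (1.34) and falls at Arid5a (-1.96), Nudt4 (-1.80), Hist1h1c (-1.40), Calm1 (-1.39) and Phf17 (-1.20). Across all genes 2066 rose and 4905 fell, around a table median of -0.25. With that median set to 0 the counts were 3120 and 3440, so that the excess of falls depends on the scaling of the table.

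At enhancers, 199 were lower and 148 higher of 5113. The lower enhancer of 13031 bp on chromosome 4, 55470334 to 55483364, lies between genes, 49.1 kb from Klf4, and had a log2 fold change of -2.59 ± 0.43 (adjusted p = 2.0e-06) in the authors' deposited table. Other enhancers among those with the smallest p-values in the authors' deposited table were lower on chromosome 3, 22284474 to 22300334, nearest Tbl1xr1 but 207.8 kb from it (-2.93 ± 0.46), and on chromosome 6, 65001346 to 65027256, 15.3 kb from Smarcad1 (-2.32 ± 0.42). A higher enhancer on chromosome 6, 51361659 to 51363623, 69.0 kb from the transcription factor gene Nfe2l3, was at 3.66 ± 0.59 in the authors' deposited table, where Nfe2l3 itself was at 2.05. For the rest of the 5 higher enhancers with the smallest p-values, the nearest tested genes were Cbx2 (-0.16), Atp2b4 (0.64), Miat (0.49) and Tsen2 (-0.52) in the authors' deposited table. Of these only Atp2b4 was called, and Miat and Tsen2 lay over 100 kb away. The 2 enhancers near Nanog with the smallest p-values did not pass (adjusted p = 0.82 and 0.9996). Where the nearest tested gene lay within 100 kb, 89 of 123 lower enhancers had a gene with a log2 fold change below 0 and 61 of 102 higher enhancers one above 0 (odds ratio 3.89, Fisher's exact test, adjusted p = 2.5e-06). Of all called enhancers, 9 higher and 6 lower lay in introns, and 18 higher and 4 lower overlapped exons, of protein-coding genes. Reads of the gene itself could be counted there. Transcription running on from neighbouring genes was not tested for LBH589.

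**Figure D2:**
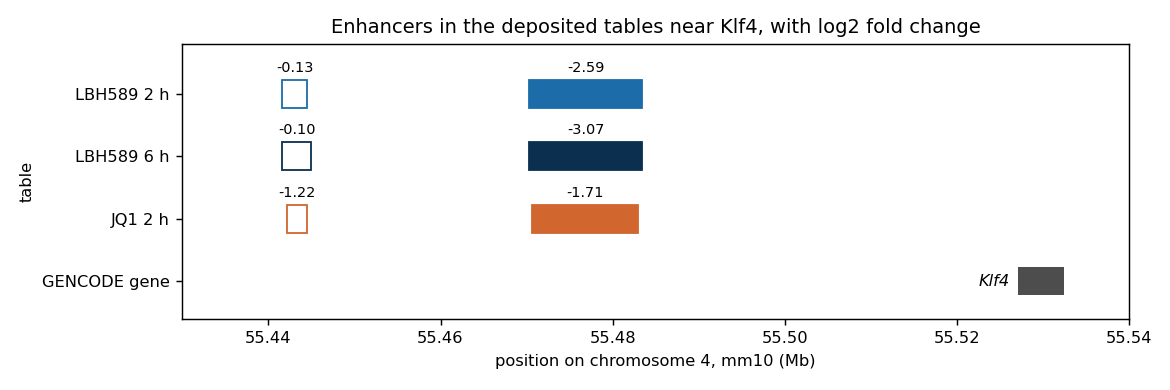
The region of chromosome 4 around Klf4 on mm10, in Mb, with the enhancers listed in the authors' deposited table for each treatment; filled boxes have an adjusted p under 0.05 and numbers are log2 fold changes. The filled enhancer, 49.1 kb from Klf4 in the LBH589 tables and, with other bounds, 49.5 kb in the JQ1 table, is at -2.59, -3.07 and -1.71.

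LBH589 for 6 h addressed the later state of the same inhibition, and the pluripotency genes again lay below control. All list results at 6 h rest on the same 2 control libraries as those at 2 h, so they are not independent repeats. Of 38 measured genes of the pluripotency list 33 were lower and 0 higher (35 lower adjusted over the list alone; median -1.70; adjusted p = 3.5e-17). Nanog was at -2.97 ± 0.23 (adjusted p = 6.7e-36) in the authors' deposited table, Pou5f1 at -2.14 ± 0.30, Zfp42 at -2.18 ± 0.20 and Klf4 at -1.98 ± 0.28. Lefty1, a NODAL target and antagonist, was at -2.89 ± 0.27 in the authors' deposited table, the transcription factor Tbx3 at -1.87 ± 0.20 and Mycn, the MYC-family member prominent in these cells, at -2.37 ± 0.21. The 8 lower genes with the smallest p-values in the authors' deposited table were Bcat1 (-2.87 ± 0.18), Tet1 (-2.73 ± 0.17), Ccnd1 (-3.64 ± 0.23), Sall1 (-3.05 ± 0.19), Tdh (-3.00 ± 0.20), Gdf3 (-3.18 ± 0.21), the Hedgehog-pathway factor Gli2 (-2.79 ± 0.19) and Prmt8 (-2.91 ± 0.20).

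Ribosome genes were lower again: 64 of 76 ribosomal protein genes (67 adjusted over the list alone; median -0.89; adjusted p = 6.9e-32), 30 of 41 ribosome biogenesis genes (30 adjusted over the list alone; adjusted p = 7.0e-12) and 8 of 10 hosts of small nucleolar RNAs (8 adjusted over the list alone; adjusted p = 0.00084). None of these lists had a higher gene, and none was matched on gene length at 6 h. Of the cell cycle genes 18 of 36 were lower (20 adjusted over the list alone; adjusted p = 0.00050), with Mybl2 at -1.91 ± 0.17 in the authors' deposited table. The histone acetyltransferase genes had 9 of 16 lower (9 adjusted over the list alone; adjusted p = 0.0088), among them Kat2b (-1.13 ± 0.18) and Crebbp (-0.77 ± 0.19) in the authors' deposited table. Of p53 targets 12 of 22 were lower and 3 higher (12 and 3 adjusted over the list alone; adjusted p for lower genes = 0.0027), and the authors' deposited table had Eda2r at -1.61 ± 0.25, Zmat3 at -1.26 ± 0.20 and, in the other direction, Sesn1 at 1.21 ± 0.20. Stress response genes were lower at 13 of 21 (13 adjusted over the list alone; adjusted p = 0.00035) and glycolysis genes at 10 of 19 (10 adjusted over the list alone; adjusted p = 0.0088). The stress list held genes of both directions, with Asns at -1.71 ± 0.20 and Ddit3, the transcription factor CHOP, at 1.52 ± 0.26 in the authors' deposited table.

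Histone genes with a Hist symbol were higher at 8 of 11 (9 adjusted over the list alone; median 1.23; adjusted p = 0.0015), and in the authors' deposited table Hist4h4 was at 2.48 ± 0.31 and Hist3h2a at 2.28 ± 0.31. The neuronal and synaptic list had 12 of 27 higher and 3 lower (13 and 3 adjusted over the list alone; adjusted p = 0.011). Its members went both ways in the authors' deposited table, with Cacna1b at 2.08 ± 0.20 and the kinase gene Camk2b at -1.38 ± 0.23. Solute carriers were higher at 49 and lower at 41 of 180 (49 and 43 adjusted over the list alone; adjusted p for higher genes = 0.021), and genes with a Zfp symbol were higher at 26 of 302 (22 adjusted over the list alone), fewer than among other genes (adjusted p = 4.7e-05). Proteasome genes were lower less often than other genes, at 2 of 45 (2 adjusted over the list alone; adjusted p = 0.043, and 0.062 with the table median set to 0). The 8 higher genes with the smallest p-values in the authors' deposited table were Plat (3.79 ± 0.27), Fam40b (3.34 ± 0.27), Pag1 (2.60 ± 0.21), Rab3b (2.82 ± 0.24), Gpr98 (2.13 ± 0.18), Nrip3 (3.70 ± 0.32), Brdt (2.35 ± 0.21) and Grk5 (2.25 ± 0.21). Plat encodes tissue plasminogen activator, and Brdt the BET protein normally found in testis.

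Of 11838 genes with an adjusted p 2163 were higher and 2292 lower, and 1013 and 864 with an absolute log2 fold change of at least 1. Under that bound the lists of cell cycle (adjusted p = 0.74), glycolysis (adjusted p = 0.44), histone acetyltransferases (adjusted p = 0.74), proteasome (adjusted p = 0.63) and neuronal genes (adjusted p = 0.055) no longer passed. Passing only under it were lower genes that respond to BET inhibitors (6 of 15 lower without it, 6 adjusted over the list alone; adjusted p = 0.19, then 0.040) and higher immediate early genes (10 of 28 higher without it, 11 adjusted over the list alone; adjusted p = 0.12, then 0.0077).

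The changes at 6 h lay close to those at 2 h. Of 10991 genes tested at both times 1568 were higher at both and 1695 lower at both, where independent lists would share 359.8 and 429.8. Opposite calls numbered 0 for genes higher and then lower and 3 for genes lower and then higher. Simulated unchanged groups that shared the control libraries had a mean of 0 shared calls, a value that leaves out real effects and does not show what shared controls add where both groups have many calls. Part of the excess over independent lists may come from the shared controls. The covariance of the fold changes across genes, which are not independent replicates, was 0.480, against 0.0393 in those simulated groups. In the test of the difference itself, over 11528 genes, 8 had a higher and 5 a lower fold change at 6 h (327 at an unadjusted p under 0.05). None of the 38 pluripotency genes passed this test, although their median difference was -0.54 and 15 had an unadjusted p under 0.05. With the covariance due to the shared controls subtracted from the variance, 56 were higher and 80 lower.

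Of the 13 genes that differed, named here after their values were seen, Trim71 had the smallest p: it encodes a stem cell RNA-binding protein, and in the authors' deposited table its log2 fold change was -0.92 ± 0.19 at 2 h and 0.70 ± 0.17 at 6 h (difference 1.62 ± 0.25, adjusted p = 1.5e-06). Its neighbour Ccr4 went from -0.63 ± 0.40 to 2.20 ± 0.27 in the authors' deposited table (difference 2.83 ± 0.49, adjusted p = 3.3e-05). The others with a higher value at 6 h were Sil1 (difference 1.21), Zfp36 (1.64), Insig1 (1.50), Malat1 (1.12), Sfi1 (1.09) and Ctgf (1.87). Those with a lower value at 6 h were Gli2 (-1.25), Mcf2 (-1.60), Tle3 (-1.24), Bnc2 (-1.14) and Pcsk6 (-1.12).

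At 6 h the pausing index rose at 35.5% and fell at 26.4% of 2292 lower genes, and fell at 58.1% and rose at 8.83% of 2162 higher genes (odds ratio 8.82, Fisher's exact test, adjusted p = 3.7e-142). As at 2 h, part of this relation is built into the index. The index rose in the authors' deposited table at Klf4 (1.42), Tbx3 (1.27), Mycn (1.01), Zfp42 (0.97) and Nanog (0.78). The rises with the smallest p-values in the authors' deposited table were at Snhg5 (2.11), the glucose transporter gene Slc2a1 (2.01), Rpl23 (1.55), Eif4a2 (1.20) and Snhg1 (1.18), and the falls with the smallest p-values at Atrnl1 (-2.66), Nudt4 (-1.54), Arid5a (-1.48), Esf1 (-1.77) and Calm1 (-0.97). Of all genes 2452 rose and 4885 fell around a table median of -0.22, or 3372 and 3609 with that median set to 0.

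Of 5516 enhancers 627 were higher and 539 lower at 6 h, but 422 and 531 with the 25% of lowest mean level left out. The enhancer 49.1 kb from Klf4 was at -3.07 ± 0.42 (adjusted p = 5.0e-10) in the authors' deposited table. An enhancer on chromosome 5, 119583653 to 119591151, 79.5 kb from Tbx3 and overlapping the antisense transcript Tbx3os1, was at -2.15 ± 0.45 in the authors' deposited table, and another 62.9 kb from Tbx3 at 1.91 ± 0.56. Near Mycn the enhancer on chromosome 12, 12985681 to 12989040, was at -1.92 ± 0.55 in the authors' deposited table. The largest rises among the 5 higher enhancers with the smallest p-values of the authors' deposited table were on chromosome 5, 139505553 to 139507493, nearest Zfand2a (5.54 ± 0.72), and on chromosome 4, 139849771 to 139853052, 16.2 kb from Pax7 (5.14 ± 0.71). Of 4183 pairs of overlapping enhancers listed at both times 169 were lower at both and 115 higher at both, and 0 had opposite calls. Independent calls would share 22.4 and 9.20, but part of that excess too may come from the shared controls. The covariance of enhancer fold changes was 0.891, against 0.158 in simulated unchanged groups with shared controls. Within 100 kb, 263 of 340 lower enhancers had a nearest tested gene below 0 and 221 of 429 higher enhancers one above 0 (odds ratio 3.63, Fisher's exact test, adjusted p = 4.5e-16). The limit given at 2 h holds here too. Of all called enhancers, 44 higher and 19 lower lay in introns, and 43 higher and 16 lower overlapped exons, of protein-coding genes.

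**Figure D3:**
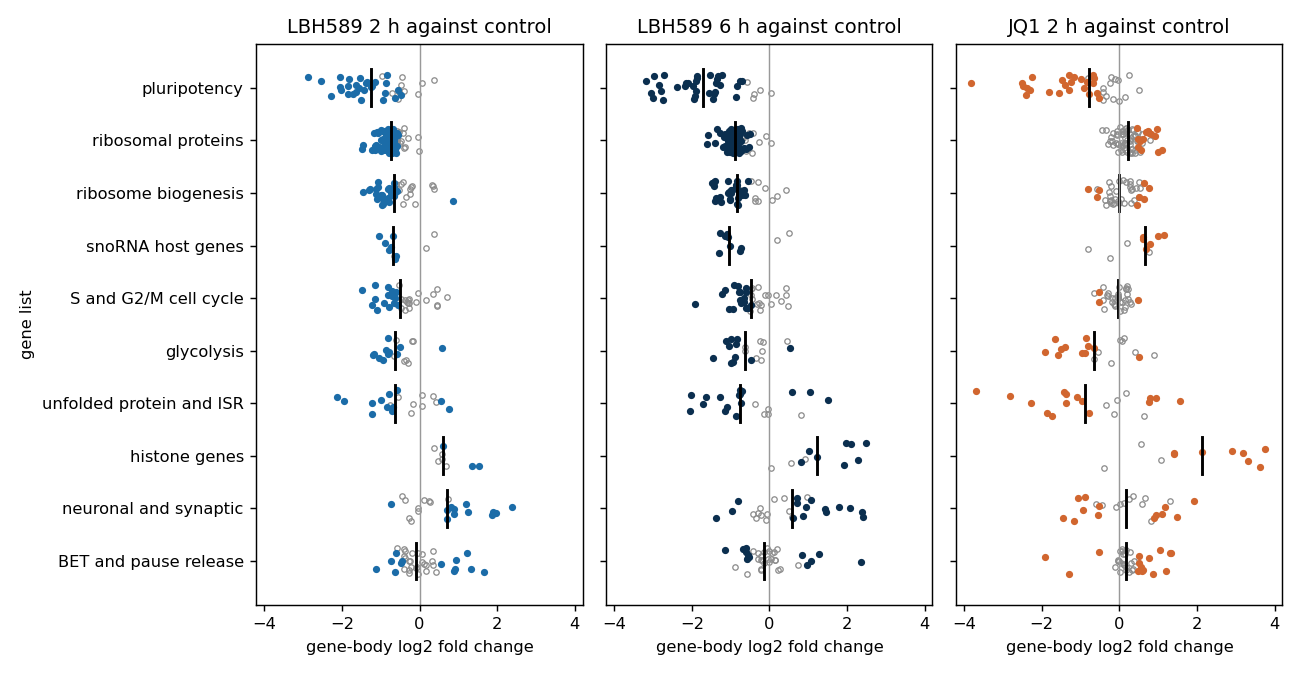
Gene-body log2 fold changes of the members of 10 gene lists in the 3 treatments; filled points have an adjusted p under 0.05 and black bars are list medians. The pluripotency medians are -1.24, -1.70 and -0.79, and those of the ribosomal protein genes are -0.73, -0.89 and 0.21.

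JQ1 for 2 h addressed BET protein inhibition, and under it too the pluripotency genes were lower. Its list results rest on the same 2 control libraries as those of LBH589, so likeness between the inhibitors is not an independent repeat. Of 38 measured genes of the pluripotency list 24 were lower and 0 higher (26 lower adjusted over the list alone; median -0.79; adjusted p = 3.3e-08). Nanog was at -2.48 ± 0.22 (adjusted p = 2.2e-26) in the authors' deposited table, Zfp42 at -1.25 ± 0.19, Pou5f1 at -0.98 ± 0.24 and Klf4 at -0.68 ± 0.26. Tbx3 (-0.43 ± 0.19, adjusted p = 0.062) and Myc (-0.01 ± 0.36, adjusted p = 0.99) did not pass in the authors' deposited table. The 8 lower genes with the smallest p-values in the authors' deposited table were Dnajc6 (-2.95 ± 0.18), Tet1 (-2.38 ± 0.16), the semaphorin receptor Nrp2 (-2.79 ± 0.20), Sulf1 (-2.34 ± 0.17), Zfp532 (-2.21 ± 0.16), Tdgf1 (-2.51 ± 0.18), Enpp3 (-2.66 ± 0.20) and Prmt8 (-2.69 ± 0.20).

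Histone genes were higher. Of 11 with a Hist symbol 8 were higher and 0 lower (9 higher adjusted over the list alone; median 2.13; adjusted p = 0.00035). Hist4h4 was at 3.75 ± 0.27 in the authors' deposited table, Hist1h2ac at 3.63 ± 0.28, Hist3h2a at 3.31 ± 0.27 and Hist1h2bc at 3.18 ± 0.22. The other higher genes with the smallest p-values in the authors' deposited table were March3 (3.04 ± 0.21), Abtb2 (2.38 ± 0.19), Neto2 (2.57 ± 0.21) and Fam40b (3.20 ± 0.28). The list of BET and pause-release factors had 12 of 37 higher and 3 lower (12 and 3 adjusted over the list alone; adjusted p = 0.044). Hexim1, which holds the elongation kinase P-TEFb inactive, was at 1.34 ± 0.22 and Brd2 at 1.20 ± 0.20 in the authors' deposited table. Host genes of small nucleolar RNAs were higher at 6 of 10 (6 adjusted over the list alone; adjusted p = 0.0088), with Snhg7 at 1.14 ± 0.21 in the authors' deposited table.

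Of ribosomal protein genes under JQ1, 14 of 76 were higher and 0 lower (9 and 0 adjusted over the list alone), fewer lower genes than elsewhere (adjusted p = 1.1e-05), while the excess of higher genes did not pass (adjusted p = 0.64). Ribosome biogenesis had 3 of 41 lower and 5 higher (3 and 4 adjusted over the list alone; adjusted p for lower genes = 0.30). Cell cycle genes had 2 of 36 lower and 1 higher (0 and 0 adjusted over the list alone; adjusted p = 0.19), and neuronal genes 7 of 24 lower and 6 higher (7 and 7 adjusted over the list alone; adjusted p for higher genes = 0.39). Of p53 targets 8 of 22 were higher (9 adjusted over the list alone; adjusted p = 0.054), with Cdkn1a at 1.92 ± 0.24 and Mdm2 at 1.28 ± 0.21 in the authors' deposited table. Glycolysis (10 of 19; 10 adjusted over the list alone; adjusted p = 0.0058) and stress response genes (11 of 20; 11 adjusted over the list alone; adjusted p = 0.0024) were lower. The authors' deposited table had the glycolytic enzyme gene Pfkp at -1.67 ± 0.20, and in amino acid synthesis Aldh18a1 at -2.82 ± 0.23 and Phgdh at -1.74 ± 0.22. Solute carriers were lower at 50 of 155 (50 adjusted over the list alone; adjusted p = 0.00033), as were 77 of 286 genes with a Zfp symbol (77 adjusted over the list alone; adjusted p = 0.0019). Proteasome genes had 1 of 44 lower (1 adjusted over the list alone), fewer than other genes (adjusted p = 0.018).

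Of 10778 genes with an adjusted p 1573 were higher and 1935 lower. With an absolute log2 fold change of at least 1 required, 440 were higher and 1086 lower, and the lists of BET and pause-release factors (adjusted p = 0.28), glycolysis (adjusted p = 0.20), small nucleolar RNA hosts (adjusted p = 0.28), proteasome (adjusted p = 0.38) and Zfp symbols (adjusted p for lower genes = 0.14) no longer passed. Genes known to respond to HDAC inhibitors, 8 of 25 higher without that bound (8 adjusted over the list alone; adjusted p = 0.11), passed under it (adjusted p = 0.0079), although for LBH589 that list passed neither with the bound (adjusted p = 0.19 at 2 h and 0.055 at 6 h) nor without it. The list of genes known to respond to BET inhibitors did not pass for JQ1, with 6 of 14 lower (6 adjusted over the list alone; adjusted p = 0.12, and 0.077 under the bound).

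Under JQ1 the pausing index rose at most of the lower genes. At 1934 genes lower under JQ1 it rose at 69.4% and fell at 3.88%, with a median change of 0.98 (bootstrap 95% interval 0.94 to 1.02). At 1573 higher genes it fell at 45.8% and rose at 26.0% (odds ratio 31.5, Fisher's exact test, adjusted p = 2.6e-239). Part of this relation is built in, because the gene body is the denominator of the index. The median gene-body change at those lower genes was -1.08. The shares are on the table's own scale. Of the 38 pluripotency genes the index rose at 32 and fell at 0. In the authors' deposited table the index rose by 2.84 at Nanog, 2.15 at Zfp42, 1.58 at Mycn, 1.56 at Tbx3, 1.53 at Klf4 and 1.12 at Pou5f1. It fell at Hexim1 (-1.18), Cdkn1a (-1.17) and Hist1h2ac (-2.83) in the authors' deposited table. By smallest p-value, the calls in the authors' deposited table were led by rises at Ddx56 (3.46), Zfp710 (3.25), Kcnk5 (3.03), Dapk3 (2.86) and Nars (2.86) and falls at Hist1h2bc (-2.80), Ppp1r10 (-1.33), Ube2k (-2.19), Rps9 (-1.10) and Arid5a (-1.44). Across all genes 4954 rose and 2318 fell around a table median of 0.31, or 3672 and 3398 with that median set to 0.

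Enhancer transcription was lower under JQ1 at 1196 of 3558 enhancers and higher at 33, around a table median of -0.98 (bootstrap 95% interval -1.03 to -0.95). With that median set to 0, 127 were lower and 201 higher, so the direction of the excess depends on the scaling of the table. The median was -1.01 outside protein-coding genes and -0.65 where an enhancer overlapped a protein-coding exon. In the authors' deposited table the enhancers with the smallest p-values were on chromosome 14, 76626832 to 76634133, 69.9 kb from Serp2 (-3.56 ± 0.55), on chromosome 6, 72915124 to 72919836, 15.1 kb from Kcmf1 (-3.77 ± 0.59), and on chromosome 4, 133101572 to 133103578, 26.9 kb from Wasf2 (-2.87 ± 0.45). Near genes fixed in advance the authors' deposited table had an enhancer on chromosome 8, 43353303 to 43380504, 46.3 kb from Zfp42, at -2.29 ± 0.42, and one on chromosome 12, 12839668 to 12844355, 97.6 kb from Mycn, at -2.69 ± 0.53. Both remained lower with the median set to 0 (adjusted p = 0.027 and 0.024). The enhancer near Klf4, at -1.71 ± 0.39 in the authors' deposited table, did not (-0.73, adjusted p = 0.24), and neither did 3 others called lower, near Zfp42 (adjusted p = 0.41), Tbx3 (adjusted p = 0.47) and Mycn (adjusted p = 0.85). Of 912 lower enhancers within 100 kb of a tested gene 584 had a nearest gene below 0, and of 22 higher enhancers 8 had one above 0 (odds ratio 1.02, Fisher's exact test, adjusted p = 1).

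**Figure D4:**
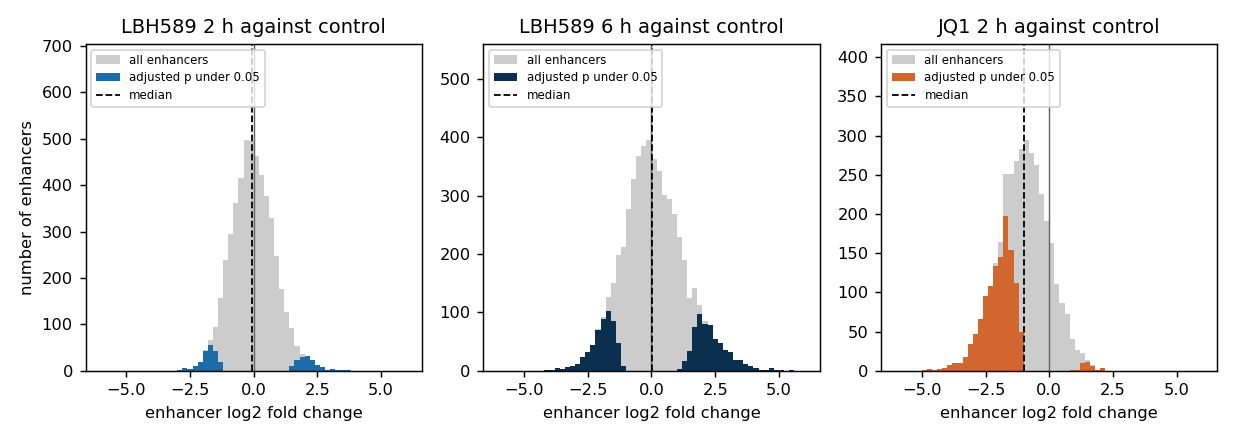
Distribution of enhancer log2 fold changes in the 3 treatments, in bins of 0.2, with called enhancers coloured and the table median dashed. The medians are -0.06, 0.01 and -0.98.

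Set against each other at 2 h, LBH589 and JQ1 had gene-body fold changes whose covariance exceeded that of simulated unchanged groups with shared controls. The doses cannot be matched, since none is given for JQ1. Of 10246 genes tested in both 575 were higher in both and 753 lower in both, where independent lists would share 240.6 and 384.2. The 216 opposite calls comprised 111 genes higher with LBH589 and lower with JQ1 and 105 the other way, against 303.6 and 304.4 expected. The covariance of fold changes across genes was 0.188, against 0.0386 in simulated unchanged groups with shared controls. Their Pearson correlation was 0.386, below the 0.496 of those groups, which hold no real effects. LBH589 at 6 h shared 607 higher and 873 lower genes with JQ1, against 235.6 and 406.2 expected. Part of these excesses may come from the shared controls. Of 3053 pairs of overlapping enhancers 99 were lower in both and 0 higher in both, where independent calls would share 65.2 and 0.128 and simulated unchanged groups with shared controls had a mean of 0 shared calls. The covariance of their fold changes was 0.0783, against 0.155 in those simulated groups, so it gives no support to a shared effect at enhancers, and the excess of lower pairs is left open.

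The test of the difference between LBH589 and JQ1 at 2 h, over 10668 genes, found 1127 with a higher and 1034 with a lower fold change under LBH589. With the covariance due to the shared controls subtracted, 2146 were higher and 2148 lower. Of ribosomal protein genes 51 of 76 were lower under LBH589 than under JQ1 and 0 higher, with a median difference of -1.02. The same direction held for 8 of 11 histone genes (median difference -1.56), 7 of 10 hosts of small nucleolar RNAs (-1.33), 13 of 41 ribosome biogenesis genes (-0.70) and 7 of 22 p53 targets (-0.66), with 0 in the other direction. Of the cell cycle genes 8 of 36 were lower and 1 higher, of neuronal genes 7 of 23 higher and 1 lower, and of solute carriers 34 of 153 higher and 12 lower. The pluripotency list had 9 of 38 lower and 2 higher. Nanog (0.42 ± 0.32, adjusted p = 0.37), Pou5f1 (-0.52 ± 0.36, adjusted p = 0.32) and Klf4 (-0.47 ± 0.37, adjusted p = 0.41) did not pass this test.

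**Figure D5:**
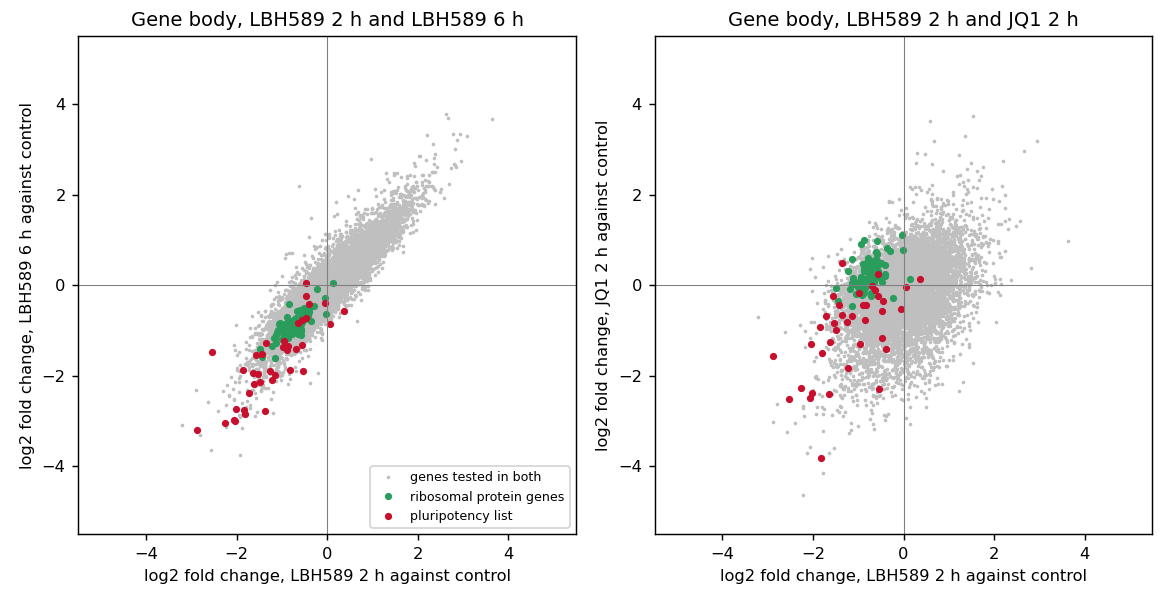
Gene-body log2 fold changes of genes tested in both comparisons, LBH589 2 h against LBH589 6 h (left) and against JQ1 2 h (right), one point per gene. Pluripotency genes lie below 0 in most cases on each axis, while ribosomal protein genes, with medians of -0.73 and 0.21, lie below 0 for LBH589 and mostly above 0 for JQ1.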

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

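The test on strongly transcribed enhancers was chosen only after the result was seen. The gene-body values in this paragraph drew attention because the effects of 2 treatments, or of 2 times, differed in a test of the difference itself; the enhancer and pausing tables were not put to that test. Between 2 h and 6 h of LBH589, 8 genes had a higher and 5 a lower fold change at 6 h. Between LBH589 and JQ1 at 2 h, 1127 genes were higher and 1034 lower under LBH589. Among the genes fixed in advance, 5 differed between the inhibitors, each lower under LBH589 than under JQ1. The differences were -0.79 ± 0.25 for Brd4 (adjusted p = 0.011), -1.17 ± 0.34 for Cdkn1a (adjusted p = 0.0066), -0.83 ± 0.29 for Hdac2 (adjusted p = 0.025), -1.17 ± 0.33 for Hexim1 (adjusted p = 0.0051) and -1.05 ± 0.29 for Mycn (adjusted p = 0.0042).

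Enhancers were lower under JQ1, with a table median of -0.98. Transcription running on from neighbouring genes was tested at 220 enhancers outside all annotated genes and over 50 kb from a gene end. Their median was -0.64 (interval -0.81 to -0.52). Few reads at weak enhancers were tested at the 25% with the highest mean level, where the median of 890 was -0.71 (interval -0.77 to -0.65). On the table's own scale these values argue against both explanations. If the table is offset, neither test can decide, since both sets lay above the table median. Enhancers within 100 kb of a tested transcription start had a median of -1.09. A single scaling offset cannot be told apart from a broad loss: the 276 enhancers whose nearest tested gene was higher had a median of -0.97 (interval -1.14 to -0.85), so these enhancers did not stand still. A wide loss of enhancer transcription under BET inhibition therefore stays a hypothesis that only an external scale could settle.

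Ribosomal protein genes were lower under LBH589 at 2 h, with a list median of -0.73. A trend with mean level is argued against, since the median was -0.76 (interval -0.84 to -0.66) once a smooth trend was removed. Short genes losing signal stays open, by a criterion outside the rule set in advance. The list median lay at percentile 1.34 of random lists matched on gene length and mean level (their median -0.56, 95% between -0.70 and -0.40). That rule used the list median alone, and by it this value counts against the explanation. The interval of the list median, -0.86 to -0.70, nevertheless reached that range. Reads shared with processed pseudogenes also stay open. Of 73 members, only 5 had exons covering under 20% of the gene (median -1.05), and they were compared with 67 others (median -0.73). The fall of this gene group may therefore reflect in part a behaviour of short, strongly transcribed genes.

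At genes lower under both inhibitors, the pausing index rose more under JQ1 than under LBH589. A rise following from the fall of the gene body alone was tested at 264 genes whose gene-body changes lay within 0.25 of each other. Their median difference of index change was 0.88 (interval 0.74 to 1.04), with medians of 0.91 for JQ1 and 0.10 for LBH589. This argues against that explanation only if the pausing tables share a scale. An offset between them cannot be told apart for part of the difference and could make the test pass on its own. At 683 genes with no gene-body call in either comparison the median difference was already 0.55. The excess over those genes was 0.32 (interval 0.18 to 0.49), and its lower bound missed the 0.3 set in advance. A block of pause release stronger under JQ1 than under LBH589 may account for that excess. It is a hypothesis found on the same data, which cannot decide it.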

How the results depend on the processing

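Chosen after the data were seen were the 50% reciprocal overlap of enhancers and, for the implied promoter-proximal change, table medians set to 0. The overlap gave 157 lower pairs for the LBH589 times in place of 169, and 95 for LBH589 2 h and JQ1 in place of 99. The medians moved the promoter-proximal change at lower genes from -0.89, -0.85 and -0.19 to -0.64, -0.61 and -0.50 for LBH589 2 h, LBH589 6 h and JQ1. No paired analysis was possible because the tables hold no values per library; for the same reason no library was left out in turn and no other tool was run. Of 86 alternatives to the main results, 64 kept the test result or stayed within 1.5 times the count, and 22 did not. With an absolute log2 fold change of at least 1, gene-body calls were 1575, 1877 and 1526 and pausing calls 2349, 2469 and 3231 for LBH589 2 h, LBH589 6 h and JQ1, shared calls were 1139 for the LBH589 times, 349 for LBH589 2 h and JQ1 and 456 for LBH589 6 h and JQ1, and 25 list tests passed in place of 44. At an adjusted p of 0.01, enhancer calls were 143, 693 and 667, shared calls 2165, 783 and 949, and differences 2 between times and 1229 between inhibitors. At 0.1 there were 540 enhancers for LBH589 2 h. These bounds lower or raise counts by construction. With each table centred on its median, JQ1 had 328 called enhancers, 201 higher and 127 lower in place of 33 and 1196. With the shared covariance subtracted, 136 genes differed between times and 4294 between inhibitors, as the smaller variance implies. The larger direction turned in several counts. With the bound on fold change, higher and lower gene bodies went from 2010 and 2093 to 885 and 690 for LBH589 2 h and from 2163 and 2292 to 1013 and 864 for 6 h, and those shared by the 2 times from 1568 and 1695 to 640 and 499. With the 25% of lowest mean level left out, enhancers at 6 h went from 627 higher and 539 lower to 422 and 531. With the shared covariance subtracted, genes higher and lower at 6 h than at 2 h went from 8 and 5 to 56 and 80, and under LBH589 than under JQ1 from 1127 and 1034 to 2146 and 2148. Among the other results, such as named genes, lists and enhancers, 1314 alternatives kept the call or value. Of the rest, 37 lost a call, 13 gained one and 1, the promoter-proximal change under JQ1, moved, and none reversed. These counts leave out list tests that passed only under an alternative, such as those given above under the bound on fold change. Another was histone deacetylase genes, higher under LBH589 2 h with the median set to 0 (Fisher's exact test, adjusted p = 0.041, otherwise 0.13). Depth per sample is unknown, so what it limits cannot be stated beyond the standard errors.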

Other observations

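Apart from the gene lists, the values in this part were chosen after the results were seen, and no explanation is offered for them. Adding the change of the pausing index to that of the gene body gives an implied change at the promoter-proximal region, on the tables' own scales. At genes lower in the gene body its median was -0.89 (interval -0.93 to -0.85) under LBH589 2 h, -0.85 (interval -0.89 to -0.81) at 6 h and -0.19 (interval -0.24 to -0.14) under JQ1. With the medians of both tables set to 0 these became -0.64, -0.61 and -0.50, so most of the contrast with JQ1 depends on the scaling of the tables. For the 38 pluripotency genes it was -0.996 and -1.22 at 2 h and 6 h of LBH589 and 0.69 under JQ1 (-0.74, -0.98 and 0.38 with the medians set to 0), and for ribosomal protein genes -0.72, -0.52 and 0.89 (-0.47, -0.28 and 0.59). The histone genes, which were higher in the gene body under JQ1, had a median pausing index change of -1.77 there.

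Markers of feeder fibroblasts, trophoblast and primitive endoderm were few among the tested genes, and none of these 3 lists passed. Of feeder fibroblast markers 1 was higher and 1 lower of 6 under LBH589 2 h, 2 and 1 of 7 at 6 h, and 0 and 1 of 5 under JQ1. Of trophoblast markers 0 were higher and 0 lower of 3, 1 and 2 of 7, and 0 and 2 of 4. Of primitive endoderm markers 0 were higher and 0, 1 and 2 lower of 4 each. In all, 28 lists passed in no treatment.

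Calls depended on gene length. Under LBH589 2 h, 9.88% of the shortest 25% of genes were higher and 18.0% lower, against 24.0% and 19.9% of the longest 25%. Under JQ1 the shares were 9.65% and 10.9% against 22.8% and 23.2%.

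Ribosomal RNA precursor transcripts, Rn45s, made up 9.10%, 7.57% and 10.2% of the summed mean counts of the gene-body tables for LBH589 2 h, LBH589 6 h and JQ1. In the authors' deposited table it was at 0.43 ± 0.18, -0.12 ± 0.20 and 0.82 ± 0.16, the last with an adjusted p of 6.4e-06. The enhancer tables for LBH589 2 h and JQ1 also list part of the mitochondrial genome, 10893 to 16299 on chromosome M, with mean counts of 90915 and 104736 and log2 fold changes of 0.05 and 0.63 that did not pass (adjusted p = 0.96 and 0.18). With the table medians set to 0 these became 0.11 and 1.61, and the JQ1 value passed (two-sided normal test, adjusted p = 0.0018).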
